A study of Homo sapiens with 14 samples.

How the data were processed

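The series holds 14 RNA sequencing samples from 2 human T cell acute lymphoblastic leukemia lines, CUTLL1 and CEM. Cells were infected with retroviruses carrying a short hairpin against JMJD3 (gene KDM6B), against UTX (gene KDM6A) or against Renilla luciferase, the control. Per the labels' protocols, RNA was purified with a Qiagen column kit, then enriched for polyadenylated RNA or depleted of ribosomal RNA, made into dUTP libraries that mark the strand, and read on an Illumina HiSeq as 50-nt single reads. Which sample received which RNA selection is not given in the sources used here. The submitters' processing notes name CASAVA, TopHat and the hg19 build, without versions. The counting program, its gene annotation and its use of strand are not given in the sources used here.

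The authors deposited 6 tables, 1 per line and per pair of hairpins, made with DEGseq per the labels. Per the file headers, each table gives every gene a raw read count for each of the pair, with 1 count column per hairpin and line. The deposited log2 ratios were normalized by the authors to the totals of the columns, as the shift between both deposited log2 columns equals the log2 ratio of the column totals. The deposited p-values and q-values come from DEGseq, and the authors' signature column marks every gene with a p-value under 0.001. Those tests compare the reads of the libraries at hand, not the conditions.

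The labels tie all replicates of a group to the same tables, and the design text speaks of matched comparisons within replicates. Which libraries each column holds is therefore not given in the sources used here, and each column was treated as the authors' pooled value for its hairpin and line. A column was the same in both tables that hold it for 5 of the 6 groups. The CUTLL1 Renilla column was not. Its total was 258014046 in the table with shJMJD3 and 144394369 in the table with shUTX. The larger column was at or above the smaller in each of the 55075 genes, higher in 30048 and equal in 25027. Subtraction left a remainder of 113619677 counts. It was used to describe the control and, after the results were seen, as a further column to set ratios against.

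Gene identifiers were matched on their stable Ensembl part to GENCODE release 29, which gave names of biotypes for 48932 of the 55075 genes. Of 40694 genes with a count in any column, 37023 matched. That release is built on another assembly than hg19, so no coordinates are given. Gene symbols are those of the deposited tables. Missing values, found only where neither column of a table had a count, were read as 0. Reads of near-identical copies, such as histone genes, and of overlapping or antisense genes are uncertain, because the rule by which the authors' counting assigned them is not given.

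The main test across lines was edgeR's quasi-likelihood F test on the deposited counts, with TMM scaling, edgeR's filterByExpr, all 6 columns, the cell line as a block and hairpin as the term of interest, which leaves 2 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The lines serve as the replicates, so these p-values measure the spread between 2 lines and not between cultures of 1 line. Each hairpin was set against the Renilla column that the authors paired it with, and the comparison of shJMJD3 with shUTX used the larger Renilla column for the estimate of spread. Within a line there is 1 value per hairpin and no replicate check. There, TMM-scaled log2 ratios with a prior count of 2 were computed, and genes at least 2-fold apart were counted among those with at least 50 counts in either column. Each ratio has an exact binomial 95% interval that covers counting error only. Scaling to column totals in place of TMM shifted all log2 ratios of shJMJD3 to Renilla by -0.14 in CUTLL1 and -0.27 in CEM, those of shUTX to Renilla by -0.03 and -0.04, and those of shJMJD3 to shUTX by -0.33 and -0.23. Ratios are given relative to TMM unless stated.

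Before the data were examined, the groups, tests, thresholds, alternatives, 26 gene lists and the rule for named genes were fixed. The rule names KDM6B, KDM6A and a panel of NOTCH pathway genes in every comparison. It adds the 8 higher and 8 lower genes with the largest smaller ratio of both lines, at 1.5-fold or more in each. It then adds up to 4 members of each list that stood apart in the same direction in both lines, and the 3 highest and 3 lowest genes of each line at 200 counts or more. Small RNAs, pseudogenes and antigen receptor genes were passed over by it, and some genes it names are not reported here.

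The lists cover NOTCH targets, MYC-driven ribosome biogenesis and growth, NF-kB targets, H3K27 demethylases with Polycomb members, H3K4 methyltransferases, HOX genes, T-ALL oncogenic transcription factors, T-ALL tumour suppressors, T cell identity and receptor signalling, S phase and G2/M, apoptosis, p53 targets, interferon-stimulated genes, the amino acid and endoplasmic reticulum stress response, cholesterol synthesis, glycolysis and hypoxia, immediate early genes, cytosolic ribosomal proteins, replication-dependent histones, non-polyadenylated RNAs, mitochondrially encoded genes, and markers of B cells, myeloid cells, erythroid cells, NK cells and fibroblast or packaging cells. In each line the median log2 ratio of a list was placed among 10000 random lists of the same size matched on level in 10 bins. A list stood apart when it lay outside the central 95% of them, which describes these libraries and is no test of the condition. Lists with fewer than 3 measured members were not placed. Across lines, camera was run on the edgeR fit with a preset correlation of 0.01 and with an estimated one, and fry beside it. Agreement between lines was described with Spearman's rho across genes, which are not independent replicates, so no p is given.

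Both procedures were tested on simulated data drawn from the real column means, with 200 genes changed by known amounts. At the spread found in the data, the across-line test for shJMJD3 against Renilla recovered 0 of 50 genes changed by a log2 of 1, 16 of 50 at 2, 42 of 50 at 3 and 50 of 50 at 5. The numbers were 0, 11, 33 and 50 for shUTX against Renilla, and 1, 22, 45 and 50 for shJMJD3 against shUTX. That spread came from all 6 columns, including the hairpin not compared. For shUTX against Renilla it was 0.412 as edgeR's biological coefficient of variation, against 0.104 with only the 4 columns compared. At a simulated spread of 0.1 the test for shUTX against Renilla recovered 49 of 50 genes changed by a log2 of 1. The within-line counting of 2-fold genes recovered 200 of 200 changed genes in each of the 4 comparisons with Renilla. Those genes had at least 200 counts, were changed by more than 2-fold and carried counting noise only, with the scaling known. Full recovery was therefore built in. It checks the counting step and does not cover differences between columns of 1 hairpin.

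Alternatives fixed in advance were DESeq2, DESeq2's size factors in edgeR, no filter, no line block, only the 4 columns compared, scaling to totals, the authors' own log2 ratios, other level and fold thresholds, a prior count of 0.5 and list means. Protein-coding genes alone and the other CUTLL1 Renilla column were added after seeing the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.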

Results

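Gene expression was measured by RNA sequencing in 2 human T cell acute lymphoblastic leukemia lines after knockdown of either H3K27 demethylase, JMJD3 (KDM6B) or UTX (KDM6A). Both enzymes remove methyl groups from lysine 27 of histone H3, a mark of Polycomb repression, and the series set out to contrast their roles in this leukemia. CUTLL1 had 3 samples with the JMJD3 hairpin, 2 with the UTX hairpin and 3 with the Renilla control hairpin, and CEM had 2 of each. The deposited values were 1 count per gene, hairpin and line, so replicate spread within a line could not be measured. Column totals were 70280185 counts for shJMJD3, 70834792 for shUTX and 104190473 for shRenilla in CEM. In CUTLL1 they were 174301733 for shJMJD3 and 101792401 for shUTX. The CUTLL1 shRenilla column had 258014046 counts where it was paired with shJMJD3 and 144394369 where it was paired with shUTX, here called the larger and the smaller control column.

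The CUTLL1 columns differed in the kinds of RNA they held. Small non-coding RNAs took 11.7% of the counts in CUTLL1 shJMJD3 and 2.52% in CUTLL1 shUTX. They took 9.29% of the larger control column, 1.92% of the smaller, and 18.7% of the remainder left when the smaller was subtracted from the larger. Protein-coding genes held 66.9% of CUTLL1 shJMJD3, 79.0% of CUTLL1 shUTX, 72.2% of the larger and 81.8% of the smaller control column. In CEM the protein-coding share was 94.1% with shJMJD3, 93.2% with shUTX and 93.0% with shRenilla, and small non-coding RNAs took at most 0.0357%. T cell genes were abundant throughout, with CD3D, a subunit of the T cell receptor complex, between 507 CPM (counts scaled to the column total) in CEM shRenilla and 1014 in the smaller CUTLL1 control column. MS4A1, the B cell surface protein CD20, had 0 counts in every column, and LYZ, the lysozyme of myeloid cells, stayed at or below 0.043 CPM.

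**Figure D1:**
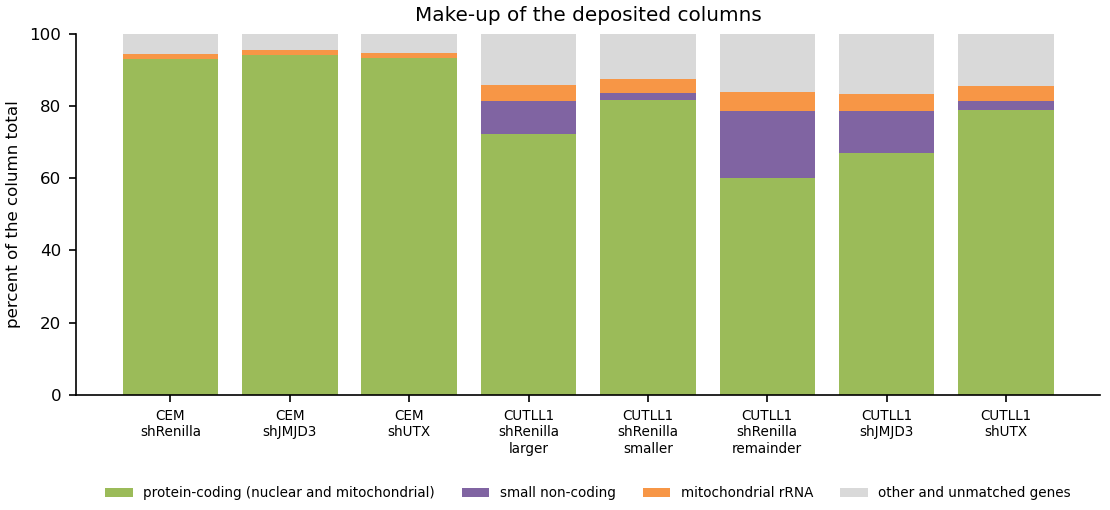
Share of each deposited count column (percent of the column total, vertical axis) taken by protein-coding genes, small non-coding RNAs, mitochondrial ribosomal RNA and all other genes, for each hairpin and line (horizontal axis); the CUTLL1 control is shown as both deposited columns and their difference. Small non-coding RNAs range from 1.92% in the smaller CUTLL1 control column to 18.7% in the remainder, and stay at or below 0.0357% in CEM.

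The gene targeted by each hairpin was lower with it in both lines. CPM values here are scaled to column totals and log2 ratios by TMM, so a ratio need not equal that of the CPM values beside it. KDM6B stood at 52.2 CPM with shJMJD3 in CEM against 206 with shRenilla, a log2 ratio of -1.71 (95% interval -1.76 to -1.66). In CUTLL1 it stood at 10.9 against 18.8 in the larger control column, a log2 ratio of -0.64 (-0.72 to -0.57). KDM6A stood at 51.5 CPM with shUTX in CEM against 136 with shRenilla, a log2 ratio of -1.36 (-1.42 to -1.31), and in CUTLL1 at 19.3 against 43.0 in the smaller control column, a log2 ratio of -1.13 (-1.20 to -1.05). The demethylase not targeted was less even. KDM6A had a log2 ratio of -0.38 (-0.42 to -0.33) with shJMJD3 in CEM and 0.00 (-0.05 to 0.05) in CUTLL1. KDM6B had one of 0.42 (0.35 to 0.49) with shUTX in CUTLL1 and -0.02 (-0.05 to 0.01) in CEM.

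**Figure D2:**
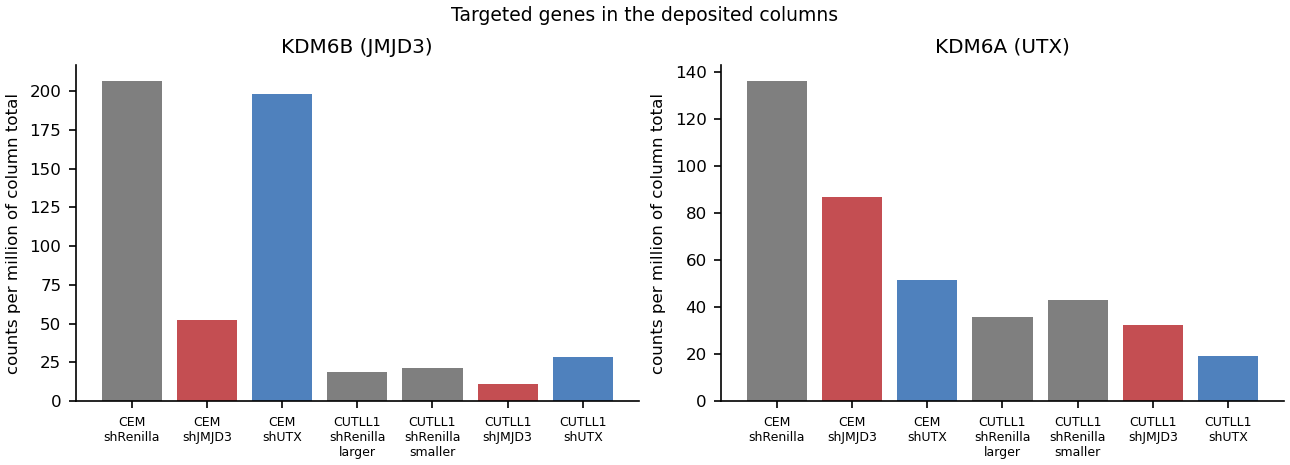
CPM, the counts scaled to the column total (vertical axes, from 0), for KDM6B and KDM6A in each deposited column (horizontal axes), with both CUTLL1 control columns; each bar is 1 column, without replicate error. KDM6B is at 52.2 in CEM shJMJD3 against 206 in CEM shRenilla, and KDM6A at 19.3 in CUTLL1 shUTX against 43.0 in the smaller control column.

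The comparison of shJMJD3 with shRenilla asks which genes depend on JMJD3. After the target itself, glycolysis and hypoxia genes were higher in both lines. The median log2 ratio of the list was 0.53 over 21 measured members in CUTLL1, with 8 members at least 1.5-fold higher and 0 lower, and 2.92 over 22 members in CEM, with 20 higher and 0 lower. The largest ratios shared by both lines were those of the glucose transporter SLC2A3 (1.05 in CUTLL1 and 2.53 in CEM), the collagen prolyl hydroxylase P4HA1 (1.05 and 4.30), the mitophagy receptor BNIP3 (0.86 and 4.87) and the aldolase ALDOC (0.77 and 2.91). Between the parts of the CUTLL1 control the same list differed by -1.80, remainder against smaller column. Set against the smaller control column, the CUTLL1 median was 0.32, with SLC2A3 at 0.89, P4HA1 at 0.57, BNIP3 at 0.33 and ALDOC at 0.32.

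MYC-driven ribosome biogenesis and growth genes had slightly lower medians in both lines, with a value of -0.25 over 29 members in CUTLL1 and -0.24 over 29 members in CEM. In CUTLL1 2 members were at least 1.5-fold lower and 0 higher, and in CEM 10 were lower and 5 higher. SRM, the spermidine synthase, stood at -1.19 and -1.33, MYBBP1A at -0.69 and -1.33, the ribosome assembly factor RRP12 at -0.50 and -0.83, and the box C/D protein NOP56 at -0.41 and -0.82. Set against the smaller control column, the CUTLL1 median of this list was -0.09 and no longer stood apart, with SRM at -0.77, MYBBP1A at -0.39, RRP12 at -0.22 and NOP56 at -0.15. With the mean in place of the median the list was at -0.04 in CEM and no longer stood apart there. Across lines camera did not call it, with an adjusted p of 0.0849 at its preset correlation and 0.979 at an estimated one. MYC itself was at -0.61 in CUTLL1 and -0.18 in CEM.

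The B cell marker list was higher, with medians of 2.15 over 4 members in CUTLL1 and 1.10 over 8 in CEM. Its members with the largest ratios in both lines were IGLL1, a part of the surrogate light chain of pre-B cells, at 2.63 and 5.80, and the leukocyte tetraspanin CD37 at 3.00 and 0.40. CD79A, a subunit of the B cell receptor, was at 34.4 CPM with shJMJD3 and 74.7 with shRenilla in CEM, and PAX5 was at or below 0.106 in every column. CD37 differed by -3.53 between the remainder and the smaller column of the CUTLL1 control.

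NOTCH pathway genes went different ways in the lines. In CUTLL1 10 of 30 measured NOTCH targets were at least 1.5-fold lower and 3 higher, with a median of -0.11 inside the range of random lists. The median was -0.16 against the smaller control column, where the list stood apart. The feedback inhibitor NRARP stood at -1.26, the repressor HEY1 at -0.99, NOTCH1 at -0.62 and the ubiquitin ligase DTX1 at -0.44, while HES1 (0.17), NOTCH3 (-0.12), IGF1R (-0.10), IL7R (-0.16) and the pre-T cell receptor chain PTCRA (0.03) lay closer to 0. Against the remainder of the control HEY1 was at 0.08 and NOTCH1 at -0.23, while NRARP was at -1.47. HES1 was at 0.96, PTCRA at 0.30 and IL7R at 0.28 against the remainder. HES1 was at -0.09 against the smaller control column, so its place near 0 depends on the control part. In CEM the list median was 0.38 over 23 members, also inside the random range. HES1 (1.44), DTX1 (1.49) and NOTCH3 (0.68) were higher there, and PTCRA (-1.41), IL7R (-0.79), IGF1R (-0.57) and NOTCH1 (-0.40) lower, while HEY1 and NRARP had at most 24 counts.

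Among all other genes, those with the largest ratio in both lines were led by the biliverdin reductase BLVRB (3.69 in CUTLL1 and 3.63 in CEM), the monoacylglycerol lipase MGLL (2.72 and 3.09), the glutathione transferase GSTM3 (2.95 and 2.61), GPSM1 (2.46 and 2.59), the sulfotransferase CHST15 (2.66 and 2.40), the Toll-like receptor chaperone UNC93B1 (2.19 and 3.06) and the cytidine deaminase APOBEC3B (2.05 and 2.56). Lower in both were the Wnt pathway protein PYGO1 (-2.12 and -3.29), SH3RF1 (-1.76 and -3.19), the calcitonin receptor-like receptor CALCRL (-1.74 and -1.95), GLT25D2 (-1.74 and -3.79), the splicing regulator ESRP1 (-1.73 and -2.38), MCF2L (-1.72 and -4.11) and the dihydropteridine reductase QDPR (-1.68 and -1.73). ANKRD34C stood at -1.86 in CUTLL1 and at -5.58 in CEM, the latter from 2 counts (95% interval -9.40 to -4.49). Of these, BLVRB, CHST15, ESRP1 and ANKRD34C also differed by -3.75, -2.20, -4.33 and -5.87 between the remainder and the smaller column of the CUTLL1 control, and UNC93B1, SH3RF1 and PYGO1 by 2.85, 2.30 and 1.46. Set against the smaller column, UNC93B1 was at 3.91 and SH3RF1 at -0.48, and against the remainder ESRP1 turned to 2.10 and ANKRD34C to 3.42. ANKRD34C had 0 counts in the remainder, and ESRP1 and BLVRB close to none. The sizes of their ratios that involve the remainder therefore depend on the prior count. In all, 287 genes were at least 1.5-fold higher and 270 lower in both lines.

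CEM showed further groups that stood apart with shJMJD3. S phase and G2/M genes had a median of 1.22, with 19 of 30 members at least 1.5-fold higher and 0 lower, among them the mitotic kinases AURKB (2.53) and AURKA (2.42). Cholesterol synthesis genes had a median of 1.38, with 18 of 20 higher, among them INSIG1 (2.88) and the squalene synthase FDFT1 (2.72). NF-kB targets had a median of 0.82, with 11 of 19 higher, such as TRAF1 (3.24) and the chemokine receptor CCR7 (1.73). The amino acid and endoplasmic reticulum stress list had a median of -1.30, with 15 of 23 lower, led by CHAC1 (-4.76), ATF5 (-4.25), the cystine transporter SLC7A11 (-4.06) and TRIB3 (-4.03). Interferon-stimulated genes had a median of -0.54, with 12 of 25 lower, among them IFIT2 (-2.70). T-ALL oncogenic transcription factors had a median of 0.68, with LYL1 at 1.52 and TAL1 at 1.46. With the mean, interferon-stimulated genes (-0.48) and T-ALL oncogenic transcription factors (0.42) no longer stood apart in CEM. In CUTLL1 the medians of these lists were 0.07, -0.10, 0.08, 0.08, 0.12 and -0.01 in the same order, all inside the random range.

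Among genes with 200 counts or more, those furthest apart in CEM were the carbonic anhydrase CA9 (7.68), P4HA2 (7.39) and the cation channel TRPM5 (7.30) on the higher side, and KIF26B (-6.55), IL31RA (-6.50) and ANKRD34C (-5.58) on the lower. In CUTLL1 they were the calcium sensor NCS1 (4.77), HS3ST3A1 (4.34) and the guanylate-binding protein GBP1 (4.27), and ANKRD18A (-3.08), PARM1 (-2.47) and FAM155B (-2.27). Between the parts of the CUTLL1 control, ANKRD18A, FAM155B and HS3ST3A1 differed by 3.57, 2.29 and 4.33, and against the smaller control column ANKRD18A was at -0.78. Other lists had CUTLL1 and CEM medians of 0.07 and -0.20 for H3K27 demethylases with Polycomb members, -0.15 and -0.25 for H3K4 methyltransferases, -0.50 and -0.27 for HOX genes, -0.04 and 0.12 for T-ALL tumour suppressors, 0.05 and 0.04 for T cell identity, 0.09 and -0.09 for apoptosis, and 0.08 and -0.21 for p53 targets, all inside the random range. Cytosolic ribosomal proteins were at 0.14 and 0.49, and histones at 0.34 and -0.60, both standing apart in CUTLL1 only. Mitochondrially encoded genes stood apart on opposite sides, at -0.19 in CUTLL1 and 0.88 in CEM, and the CUTLL1 median was 1.14 against the smaller control column. With the mean, mitochondrially encoded genes were at 0.85 in CEM and no longer stood apart there. Myeloid, NK and fibroblast markers were at 0.11, 0.61 and 0.28 in CUTLL1 and 1.04, 0.49 and 0.93 in CEM. Of these, NK markers stood apart in CUTLL1, and myeloid and fibroblast markers in CEM, but with the mean only the myeloid markers did. Fewer than 3 erythroid markers reached the level minimum in either line, and across lines that list had an adjusted p of 0.979 in camera with an estimated correlation. Scaling to column totals lowered these medians, so the smallest positive ones turned negative with it.

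In CUTLL1 727 genes were at least 2-fold higher and 460 lower with shJMJD3 among 19772 considered, and in CEM 1916 were higher and 2399 lower among 16998. With column totals as the scaling the numbers were 575 and 659 in CUTLL1 and 1285 and 3499 in CEM. Protein-coding genes gave 504 and 209 in CUTLL1 and 1433 and 1463 in CEM, and of the CUTLL1 genes 491 lay above both parts of the control and 169 below both. The larger control column is the sum of both parts, so this is partly built in. At least 2-fold beyond both parts lay 358 of the higher and 64 of the lower genes. Set against the smaller control column, the CUTLL1 numbers were 2699 and 182. The authors' deposited table called 3521 genes higher and 9248 lower in CUTLL1, and 4652 and 9995 in CEM. Across lines, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 24003 genes, with 936 at an unadjusted p under 0.05 and a smallest adjusted p of 0.800, while DESeq2 called 115. KDM6B had a log2 ratio across lines of -1.15 with a standard error of 0.30 and an adjusted p of 0.800 in the same edgeR test. Camera with its preset correlation called 7 of 26 lists, of which glycolysis and hypoxia had an adjusted p of 5.86e-12 and S phase and G2/M one of 7.08e-08. With an estimated correlation it called 0, with an adjusted p of 0.821 for both. Adjusted over the list alone, 1 gene passed, in the B cell marker list, against 0 over all genes tested.

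The comparison of shUTX with shRenilla asks which genes depend on UTX, and in CEM its differences were smaller than those of shJMJD3. In CUTLL1 the order depended on which control column was used. Glycolysis and hypoxia genes were again higher in both lines, with a median of 0.60 over 21 members in CUTLL1, of which 12 were at least 1.5-fold higher, and 0.21 over 21 members in CEM, of which 3 were higher and 1 lower. BNIP3 stood at 0.90 in CUTLL1 and 0.74 in CEM, P4HA1 at 0.70 and 0.89, the lactate dehydrogenase LDHA at 0.42 and 0.81, and the enolase ENO1 at 0.57 and 0.38. In CEM both hairpins were set against the same control column, so part of what their ratios share may come from that column's own error. In CUTLL1 the smaller control column was at or below the larger in every gene. The CUTLL1 ratios of both hairpins may therefore share control reads too.

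NOTCH targets were slightly lower in both lines, with medians of -0.12 over 29 members in CUTLL1 and -0.08 over 23 in CEM. In CUTLL1 4 members were at least 1.5-fold lower and 1 higher, and in CEM 2 were lower and 1 higher. The ligands DLL1 (-0.72 and -0.14) and JAG1 (-0.15 and -0.55), PTCRA (-0.12 and -1.76) and NOTCH3 (-0.16 and -0.12) were lower in both. NOTCH1 was at -0.29 and -0.08, DTX1 at -0.54 and -0.12, HES1 at 0.23 and -0.02, MYC at -0.13 and -0.03, IGF1R at 0.20 and -0.06, and IL7R at 0.20 and -0.42, while NRARP stood at -0.48 and HEY1 at -0.49 in CUTLL1. Set against the larger control column, the CUTLL1 list median was -0.04 and no longer stood apart, with DLL1 at -0.17, JAG1 at 0.17 and HES1 at 0.50. At a level minimum of 10 the CUTLL1 median of NOTCH targets for shUTX against shRenilla was -0.10, and it no longer stood apart either.

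Cytosolic ribosomal protein genes and mitochondrially encoded genes were slightly higher in both lines. The ribosomal medians were 0.18 in CUTLL1 and 0.21 in CEM, with RPL13 at 0.28 and 0.28, RPS16 at 0.41 and 0.26, and RPLP1 at 0.48 and 0.23. The mitochondrial medians were 0.19 and 0.28, with MT-ND4 at 0.31 and 0.31, MT-ND4L at 0.28 and 0.54, MT-CYB at 0.19 and 0.32, and MT-ND5 at 0.18 and 0.46. Against the larger control column both CUTLL1 medians changed sign, to -0.28 for the ribosomal and -0.997 for the mitochondrial list. The MYC list was at -0.34 in CUTLL1, where it stood apart, and 0.03 in CEM. T cell identity genes were at -0.03 in CUTLL1 and -0.12 in CEM, and stood apart in CEM only, where S phase and G2/M genes were at 0.17.

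Among all other genes, the largest ratios shared by both lines belonged to P4HA2 (1.53 and 3.54), the basement membrane proteoglycan HSPG2 (1.38 and 1.90), CCDC113 (1.23 and 1.20), EPSTI1 (1.19 and 1.18), TMEM56 (1.13 and 0.91), cyclin E1 (CCNE1, 1.01 and 1.08), PPFIA4 (0.97 and 2.24) and the mitochondrial adenylate kinase AK4 (0.95 and 1.87). Lower in both were the TRAIL receptor TNFRSF10A (-2.91 and -1.53), the chemokine receptor CXCR3 (-1.35 and -0.85), the natural cytotoxicity receptor NCR3 (-0.99 and -0.90), CHRNA10 (-0.96 and -0.84), NEGR1 (-0.92 and -1.46), the transporter ABCC2 (-0.88 and -0.78) and the prostaglandin receptor PTGER3 (-0.85 and -1.86). Between the remainder and the smaller column of the CUTLL1 control, P4HA2, EPSTI1, PPFIA4 and TNFRSF10A differed by -3.47, -3.78, -2.99 and -3.30. P4HA2 and EPSTI1 had 0 counts in the remainder. Against the larger control column NEGR1 was at -0.41, PTGER3 at -0.49 and CCNE1 at 0.53, and against the remainder TNFRSF10A was at 0.40, NEGR1 at 1.73, PTGER3 at 0.55 and CCNE1 at -0.06. In all, 47 genes were at least 1.5-fold higher and 12 lower in both lines. Among genes with 200 counts or more, those furthest apart in CUTLL1 were FAM115C (1.56), CACNB4 (1.52) and stanniocalcin 1 (STC1, 1.51), and syndecan 4 (SDC4, -1.37), PRKAR2A (-1.21) and RIMBP2 (-1.19). SDC4 and RIMBP2 stood at -0.75 and -0.72 against the larger control column, and at 4.63 and 0.96 against the remainder. SDC4 had 0 counts in the remainder, so the size of 4.63 depends on the prior count. STC1 differed by -6.24 between the control parts. In CEM they were SDK2 (3.63), PPFIA4 (2.24) and NDST1 (1.88), and the potassium channel KCNK17 (-3.41), ZNF683 (-3.02) and HKDC1 (-2.07).

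In CUTLL1 111 genes were at least 2-fold higher and 46 lower with shUTX among 16886 considered, and in CEM 136 were higher and 206 lower among 16791. The authors' own log2 ratios gave 107 and 74 in CUTLL1. Set against the larger control column, the CUTLL1 numbers were 253 and 2552. Of 78 protein-coding genes 2-fold higher in CUTLL1, 71 lay above both parts of the control, and of 21 lower ones 13 lay below both. These genes were picked against the smaller column, so only the remainder could go against them. At least 2-fold beyond both parts lay 52 of the higher and 5 of the lower genes. The authors' deposited table called 2706 genes higher and 5100 lower in CUTLL1, and 2861 and 4086 in CEM. Across lines, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 23112 genes, with 39 at an unadjusted p under 0.05, and DESeq2 called KDM6A alone. KDM6A had a log2 ratio across lines of -1.25 with a standard error of 0.17 and an adjusted p of 1 in the same edgeR test. With only the 4 columns of these groups the edgeR test called 16 genes, 12 higher and 4 lower, KDM6A among them with an adjusted p of 0.000333. The spread that edgeR estimated was then 0.104, against 0.412 with all 6 columns. Not all of these 16 calls rested on both lines. KCNK17, with 0 counts in both CUTLL1 columns compared, had an adjusted p of 0.000218 in this 4-column edgeR test. SDK2, with 0 counts in CUTLL1 shUTX and 1 in the smaller control column, had one of 0.000715. Camera with its preset correlation called 5 of 26 lists, of which ribosomal proteins had an adjusted p of 2.17e-06, glycolysis and hypoxia one of 0.000856 and the mitochondrial list one of 0.00501. With an estimated correlation it called 0, with an adjusted p of 0.766 for each of them, and the NOTCH list had an adjusted p of 0.787. Adjusted over the list alone, 1 gene passed, KDM6A in the demethylase and Polycomb list, against 0 over all genes tested.

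The direct comparison of shJMJD3 with shUTX asks where the knockdowns differ. KDM6B was lower with shJMJD3 by log2 ratios of -1.04 in CUTLL1 and -1.69 in CEM, and KDM6A higher by 1.09 and 0.99. Amino acid and endoplasmic reticulum stress genes were lower with shJMJD3 in both lines. The list median was -0.51 in CUTLL1, with 10 of 23 members at least 1.5-fold lower and 1 higher, and -1.08 in CEM, with 16 of 23 lower and 1 higher. The asparagine synthetase ASNS stood at -1.17 and -2.05, the transcription factor ATF5 at -1.10 and -4.35, the pseudokinase TRIB3 at -1.08 and -4.38, and HERPUD1, a part of the machinery that degrades misfolded proteins, at -1.06 and -2.19. Between the remainder and the smaller column of the CUTLL1 control this list differed by -1.53.

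B cell markers were higher with shJMJD3, with medians of 2.04 over 4 members in CUTLL1 and 1.05 over 8 in CEM, and IGLL1 at 2.63 and 4.80 and CD37 at 2.87 and 0.30. With the mean in place of the median B cell markers were at 1.58 in CUTLL1 and no longer stood apart there. Several lists took opposite directions in the lines. Glycolysis and hypoxia genes were at -0.40 in CUTLL1 and 2.83 in CEM, and cholesterol synthesis genes at -0.16 and 1.48. Between the remainder and the smaller column of the CUTLL1 control the glycolysis list differed by -1.80, the direction of its CUTLL1 ratio. NOTCH targets were at -0.25 in CUTLL1, with 6 of 29 members at least 1.5-fold lower and 3 higher, and at 0.41 in CEM, with 3 of 22 lower and 7 higher. HES1 was at -0.31 and 1.46, DTX1 at 0.07 and 1.61, and NOTCH3 at 0.01 and 0.80, whereas NOTCH1 (-0.45 and -0.32), MYC (-0.51 and -0.14), IL7R (-0.50 and -0.37) and IGF1R (-0.26 and -0.51) were lower in both. PTCRA stood at 0.08 and 0.35, and NRARP at -0.55 and HEY1 at -0.84 in CUTLL1. The MYC list was at 0.30 in CUTLL1 and -0.37 in CEM. Its CUTLL1 value turned to -0.04 with column totals as the scaling, which shifted all CUTLL1 ratios of this comparison by -0.33. With the mean the MYC list was at 0.42 and -0.08 and stood apart in neither line, and NOTCH targets were at 0.12 in CEM and no longer stood apart there. T-ALL oncogenic transcription factors had a median of -0.34 and a mean of 0.14 in CUTLL1, and a median of -0.05 at a level minimum of 10. S phase and G2/M genes were at 0.02 in CUTLL1 and 1.09 in CEM. HOX genes stood apart at -0.86 in CUTLL1, and in CEM 3 myeloid markers stood apart at 1.69 and fibroblast markers at 0.89. With the mean, myeloid markers were at 1.13 and fibroblast markers at 0.40 in CEM, and neither stood apart. Ribosomal protein and mitochondrially encoded genes were at 0.43 and 0.89 in CUTLL1, and at 0.37 and 0.65 in CEM, where neither stood apart.

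Among all other genes, those higher with shJMJD3 in both lines were led by the heat shock protein HSPA1A (3.31 and 5.83), the phosphoglycerate mutase PGAM1 (3.04 and 3.25), FAM72B (3.90 and 2.42), the natural cytotoxicity receptor NCR3 (2.35 and 3.13), UNC93B1 (3.30 and 2.29), MBP (3.67 and 2.28) and the lymphocyte surface protein CD48 (2.22 and 3.24). Lower were the endocytic protein EHD3 (-3.29 and -4.30), CALCRL (-2.71 and -1.75), ESRP1 (-2.36 and -2.86), PARM1 (-2.17 and -3.23), PARD3B (-2.09 and -2.82), GLT25D2 (-2.09 and -4.34) and the guanine exchange factor TRIO (-1.80 and -3.30). ANKRD34C stood at -1.81 in CUTLL1 and at -5.46 in CEM, the latter from 2 counts (95% interval -9.44 to -4.51). PGAM1, FAM72B, HSPA1A and UNC93B1 also differed by 4.23, 4.59, 3.21 and 2.85 between the remainder and the smaller column of the CUTLL1 control, and CD48, ESRP1 and ANKRD34C by -4.73, -4.33 and -5.87. ANKRD34C had 0 counts in the remainder. In all, 346 genes were at least 1.5-fold higher and 272 lower in both lines. In CUTLL1 the histone genes HIST2H2AA4, HIST2H3C and HIST2H3A had 156645, 153676 and 153538 counts with shJMJD3 and 0 with shUTX, and are uncertain because near-identical copies share their reads. The same split lay within the control, with 0 counts in the smaller column and log2 ratios of 16.31, 16.34 and 16.34 for the remainder against it. On the lower side were SYNDIG1 (-2.25), STC1 (-1.97) and the kinase scaffold KSR2 (-1.82). Among genes with 200 counts or more, the furthest in CEM were the heat shock gene HSPA6, at 8.44 from 1216 against 2 counts (95% interval 7.64 to 12.54), DPEP1 (6.76) and adrenomedullin (ADM, 6.44), and KIF26B (-7.19), IL31RA (-7.11) and MAP1B (-5.37).

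In CUTLL1 2680 genes were at least 2-fold higher and 306 lower among 18287 considered, and in CEM 1875 were higher and 2105 lower among 16229. With column totals as the scaling the numbers were 2318 and 860 in CUTLL1 and 1317 and 2966 in CEM. Protein-coding genes gave 922 and 222 in CUTLL1, and 1342 and 1418 in CEM. The authors' deposited table called 4049 genes higher and 11350 lower in CUTLL1, and 4636 and 9007 in CEM. Across lines, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 24003 genes, with 1945 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0633. DESeq2 called 310, 212 higher and 98 lower. Without a filter on low counts edgeR called 55 genes, all higher. Among them were small RNA genes such as 7SK and RNU1-2, and the histone copies HIST2H2AA4, HIST2H3C and HIST2H3A. These histone copies had 0 counts in both CEM columns compared, so their calls rested on CUTLL1 alone, where the control was split in the same way. Camera with its preset correlation called 7 of 26 lists, of which the stress list had an adjusted p of 5.68e-07 and B cell markers one of 0.0456. With an estimated correlation it called 0, with an adjusted p of 0.987 for both. Adjusted over the list alone, 0 genes passed, as over all genes tested.

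**Figure D3:**
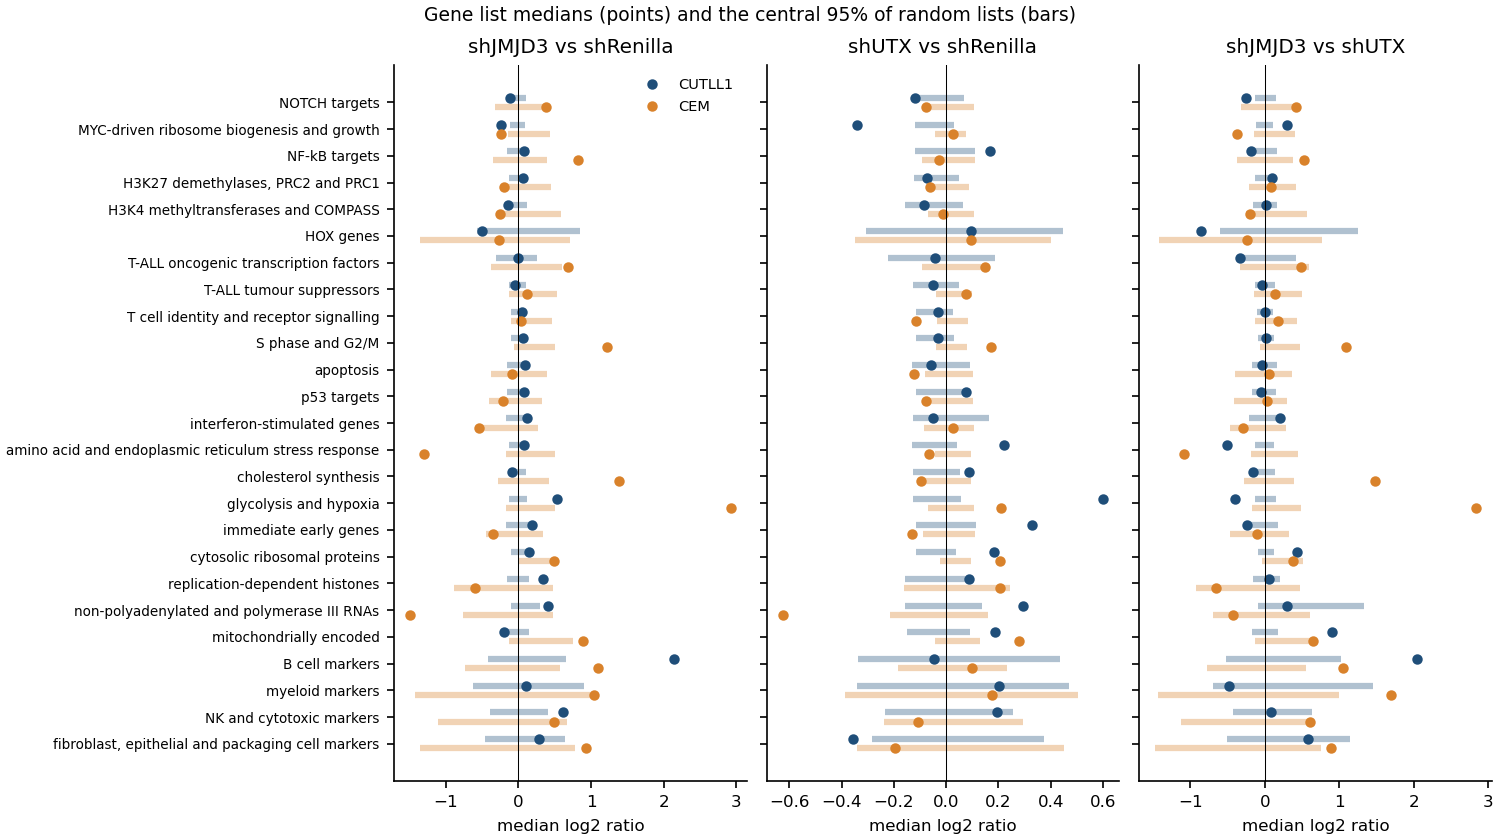
Median log2 ratio of each gene list (points, horizontal axes, whose ranges differ between panels) in CUTLL1 and CEM for the 3 comparisons; bars span the central 95% of 10000 random lists matched in size and level. Glycolysis and hypoxia genes lie at 0.53 in CUTLL1 and 2.92 in CEM with shJMJD3 against shRenilla, and at 0.60 and 0.21 with shUTX against shRenilla.

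The ratios of the lines could be compared across genes because CUTLL1 and CEM share no libraries. For shJMJD3 against shRenilla, Spearman's rho was 0.271 over 15882 genes. Both lines had 123 genes 2-fold higher, where independent lists would share 48.2, and 74 genes 2-fold lower, where they would share 22.7. For shUTX against shRenilla, rho was 0.147 over 15153 genes, with 5 genes higher in both (P4HA2, HSPG2, CCDC113, EPSTI1 and CCNE1) against 0.352 and 2 lower (TNFRSF10A and KDM6A) against 0.132. For shJMJD3 against shUTX, rho was 0.0851 over 15113 genes, with 205 higher in both against 127 and 90 lower against 22.7. Among protein-coding genes, the shUTX ratios of CUTLL1 had a rho of 0.218 with the shJMJD3 ratios of CEM, and the shJMJD3 ratios of CUTLL1 one of -0.0359 with the shUTX ratios of CEM. With the same hairpin in both lines, rho among protein-coding genes was 0.291 for shJMJD3 and 0.171 for shUTX against shRenilla. An excess of shared 2-fold genes was not particular to matched hairpins. Among protein-coding genes, CUTLL1 shUTX and CEM shJMJD3 shared 29 higher genes against 6.03. The remainder set against the smaller CUTLL1 control column, both of 1 hairpin, shared 158 lower genes with CEM shJMJD3 against 71.4, and 81 higher against 77.4. The rho of that pair was -0.0929.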

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

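The tests of explanations in this part, and the use of the other CUTLL1 control column and of the control parts, were chosen after the results were seen, while the list medians, column totals and the mean were planned. None of the differences between lines given here was tested, since each line has 1 value per hairpin.

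The larger CUTLL1 Renilla column holds 113619677 counts beyond the smaller, a part of the control absent from the column that the authors paired with shUTX. This remainder had 18.7% small non-coding RNA, and 4449 genes, 1792 of them protein-coding, were at least 2-fold apart between it and the smaller column. The pattern weighed here is the 2680 CUTLL1 genes at least 2-fold higher with shJMJD3 than with shUTX. Of 2463 that could be measured in the control parts, 86.4% were also at least 2-fold higher in the remainder than in the smaller column, against 3.71% of 15388 other genes, so columns that mix kinds of library in different shares are a candidate explanation for most of this set. An effect of the hairpins common to both lines stays open: 17.3% of the genes measured in CEM were 2-fold higher there, against 10.1% of the others, and a difference between cultures is open too.

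Glycolysis and hypoxia genes were at -0.40 in CUTLL1 and 2.83 in CEM with shJMJD3 against shUTX, opposite in direction. The CUTLL1 value had the direction of the -1.80 by which the remainder of the control differed from the smaller column. The pattern weighed here is their higher level in CEM with shJMJD3 against shRenilla, a median of 2.92. Scaling as its cause is argued against, since column totals left a median of 2.65 and moved all genes by 0.27. A difference in library kind like that within the CUTLL1 control is argued against by the stress list. Between the control parts it went the same way as glycolysis genes, at -1.53 and -1.80. In CEM it went the other way from them, at -1.30 against 2.92. The value of -1.80 lies between parts of 1 hairpin that also differ in kind of RNA, so it cannot test a difference between cultures. Cultures that differed in oxygen, density or medium stay open for the CEM difference. They cannot be told apart from an effect of JMJD3, because the deposited values give no replicates.

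NOTCH targets were at -0.25 in CUTLL1 and 0.41 in CEM with shJMJD3 against shUTX, and with the mean the CEM value was 0.12 and no longer stood apart. The pattern weighed here is the 10 NOTCH targets at least 1.5-fold lower with shJMJD3 than with shRenilla in CUTLL1, among them NRARP, HEY1, NOTCH1 and MYC. Their median ratio to whichever control part was nearer was -0.49, and 8 of 10 lay below both parts, 4 of them by 1.5-fold or more. The genes were picked against the larger control column, the sum of both parts, so lying below both is partly built in. The control parts may account for some members, and the others are left open. In CEM, 5 of these genes could be measured, with a median of 0.63 and 2 below 0, so an effect of JMJD3 on these genes in both lines is neither shown nor excluded with so few members.

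Other lists took opposite directions in the lines. With shJMJD3 against shUTX, the MYC list was at 0.30 in CUTLL1 and -0.37 in CEM, and cholesterol synthesis at -0.16 and 1.48. With column totals the MYC list was at -0.036 and -0.61. That scaling shifted all CUTLL1 ratios of this comparison by -0.33, so the change of sign says nothing about the list's place among other genes. With the mean the MYC list stood apart in neither line. With shUTX against shRenilla, the amino acid and endoplasmic reticulum stress list was at 0.22 in CUTLL1 and -0.067 in CEM, cholesterol synthesis at 0.085 and -0.096, immediate early genes at 0.33 and -0.13 (with the mean no longer apart in CEM), and non-polyadenylated RNAs at 0.29 and -0.63. With shJMJD3 against shRenilla, non-polyadenylated RNAs were at 0.41 in CUTLL1 and -1.49 in CEM, and mitochondrially encoded genes at -0.19 and 0.88. Small non-coding RNAs took at most 0.0357% of a CEM column, and 1.92% and 18.7% of the parts of the CUTLL1 control. The directions of the non-polyadenylated list cannot be told apart from this make-up of the columns. Against the smaller control column the mitochondrial median in CUTLL1 was 1.14, the same direction as in CEM, where with the mean it no longer stood apart.

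Single genes also went opposite ways. With shJMJD3 against shRenilla, 84 genes were 2-fold higher in CUTLL1 and 2-fold lower in CEM, and 14 the reverse. With shJMJD3 against shUTX the numbers were 123 and 33. In the first comparison 455 of 15882 genes were higher and 177 lower in CUTLL1, and 1684 higher and 2035 lower in CEM. In the second, of 15113, they were 1185, 195, 1615 and 1763. No number for independent lists was computed for opposite directions, so these counts do not show more reversal than unrelated ratios would give. With shJMJD3 against shUTX, KSR2 was at -1.82 in CUTLL1 and 3.01 in CEM, and ADM at -1.11 and 6.44. ADM also differed by -5.72 between the remainder and the smaller column of the CUTLL1 control, the direction of its CUTLL1 ratio.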

How the results depend on the processing

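Protein-coding genes alone and the other CUTLL1 Renilla column are alternatives chosen after seeing the data. No paired analysis was possible because the deposited tables give 1 column per hairpin and line and no column per replicate, so leaving out each replicate and a replicate block could not be run either. The cause of a moved value was not tested, except where a lower or higher threshold itself admits more or fewer genes.

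Across lines edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes in each comparison, with 936, 39 and 1945 at an unadjusted p under 0.05 for shJMJD3 against shRenilla, shUTX against shRenilla and shJMJD3 against shUTX. DESeq2 called 115, 1 and 310. Only the 4 columns compared gave 16 genes for shUTX against shRenilla, among them KCNK17 with 0 counts in CUTLL1. No filter gave 55 for shJMJD3 against shUTX, among them histone copies with 0 counts in CEM. The other edgeR alternatives called 0.

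For shJMJD3 against shRenilla in CUTLL1, the number of genes past the fold threshold was 3121 at a level minimum of 10, 579 at 200, 3141 at 1.5-fold, 713 among protein-coding genes and 2881 with the other control column. In CEM it was 6479 at a minimum of 10 and 7875 at 1.5-fold. For shUTX against shRenilla in CUTLL1 it was 1240, 51, 967, 99 and 2805 in the same order, and 711 among protein-coding genes with the other control column. In CEM it was 1440, 99, 1234 and 191 for the first 4 of these. For shJMJD3 against shUTX in CUTLL1 it was 5270, 1905, 4684 and 1144, and in CEM 5999 at a minimum of 10 and 7403 at 1.5-fold.

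Agreement between lines for shJMJD3 against shRenilla had a rho of 0.218 at a level minimum of 10, 0.305 at 200, 0.291 among protein-coding genes, 0.197 with the other control column and 0.231 with both. For shUTX against shRenilla it was 0.110 at a minimum of 10, 0.171 among protein-coding genes and 0.101 with both. KDM6B was at -0.79 in CUTLL1 and -1.98 in CEM with column totals for shJMJD3 against shRenilla.

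Of 68 list medians that stood apart, 65 still did at a level minimum of 10, and 3 kept their direction without standing apart. With totals 67 still did and the MYC list in CUTLL1 for shJMJD3 against shUTX turned to -0.036. That change of sign came with a shift of all genes there by -0.33 and says nothing about the list's place among them. With the mean 52 still did, 15 kept their direction without standing apart, and T-ALL oncogenic transcription factors in CUTLL1 in that comparison turned to 0.139. With the mean, 1 list stood apart in both lines for shJMJD3 against shUTX. Of the named genes' ratios, 119 moved past their counting interval with totals, 3 with a prior count of 0.5 and 62 with the other control column, against 140, 256 and 29 that did not. Depth limits ratios with few counts in a column, such as those of ANKRD34C in CEM shJMJD3 and HSPA6 in CEM shUTX, each with 2 counts. Further examples are TRPM5 in CEM shRenilla and TNFRSF10A in CUTLL1 shUTX, each with 4 counts. PYGO1 and PARM1 had 5 counts and KIF26B 6 in CEM shJMJD3, and EHD3 had 6 in CUTLL1 shJMJD3.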

Other observations

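The genes in this part were chosen after their values were seen. Interferon-stimulated genes did not stand apart as a list in CUTLL1 with shJMJD3, with a median of 0.12 against shRenilla, yet 8 of 24 measured members were at least 1.5-fold higher. Those with the largest ratios were OAS1 (3.89), OAS3 (3.49), OASL (3.26) and OAS2 (2.99) of the antiviral oligoadenylate synthetase family, the tetherin BST2 (3.58), the antiviral GTPase MX1 (2.81) and IFIT3 (2.74). ISG15 (-0.48), IFI27 (-0.37) and IFIH1 (-0.74) lay lower. OAS2 and OAS3 differed by only 0.23 and 0.47 between the parts of the CUTLL1 control, whereas OAS1 differed by -2.28, OASL by -2.59 and BST2 by -4.39. In CEM with shJMJD3, MX1 was at -1.28, OASL at -1.34, OAS1 at 0.47 and OAS3 at 1.12.

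T cell identity genes had a median near 0 in CEM with shJMJD3, with 7 of 32 members at least 1.5-fold higher and 8 lower, a share close to that of all genes, of which 7875 of 16998 were past 1.5-fold. The coreceptor CD4 was at 1.97, CD27 at 2.55 and the terminal transferase DNTT at 1.47. The coreceptor CD8A was at -2.42, the thymocyte marker CD1A at -1.96, and the recombinase genes RAG1 and RAG2 at -2.25 and -2.07. In CUTLL1 with shUTX, 20 of 21 measured immediate early genes lay above 0, with EGR1 at 0.80, FOS at 0.72 and FOSB at 0.71, and in CEM EGR1 was at 0.86, FOS at 0.07 and FOSB at -0.20, with a list median of -0.13 that stood apart on the lower side.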
